A study of Homo sapiens with 4 samples.

How the data were processed

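Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the genomic sites of FOXK2, a forkhead transcription factor, in MCF-7 cells, an estrogen receptor-positive luminal breast cancer line. The series holds 4 samples. They are a FOXK2 immunoprecipitation and an input labelled as MCF-7, and a FOXK2 immunoprecipitation and an input whose source is labelled only as a cell line. Each group has 1 sample. Only the MCF-7 FOXK2 immunoprecipitation came with a processed file here, a list of peaks, and the other 3 samples were not analysed here. The labels' protocols describe goat IgG as the control precipitation, whereas the paired sample is labelled as input with no antibody, so which control entered peak calling is not given in the sources used here.

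Per the submitters' processing notes, CASAVA, Bowtie2 and MACS were used and the genome build was hg19. Versions, settings and the order of steps are not given in the sources used here. The deposited list gives the chromosome, start and end of each peak, a peak name that begins with MACS, and 1 score per peak. The deposited score is the peak caller's own value. In the BED output of MACS such a score is 10 times the negative log10 of the peak's p-value, and this reading is inferred from the peak names and not stated by the labels. The list held peaks numbered from 1 to 11717 without a missing number, so none had been removed from within it after numbering. Whether peaks with higher numbers were left out is unknown. Scores started at 30 and ended at 3100, a value shared by 3 peaks. The file gives no read counts, fold enrichments, summits or false discovery rates, so the depth behind each peak is unknown. A score depends on depth as well as on enrichment and was used to rank and filter peaks within this list. In addition, the shares of peaks above given scores were set against those expected if the scores were calibrated p-values on this scale.

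Starts were converted to 1-based positions and the midpoint of a peak stood for its centre. Neither the sequence nor a gene annotation of hg19 was used here. The gene table that was at hand refers to GRCh38 and its positions were not set against the peaks. Promoter shares, motif tests and gene list tests that had been planned before the data were examined were therefore not made, and no gene is named under any peak. For the same reason only the first part of the planned rule for named items, the 10 peaks with the highest scores, could be applied. Other peaks and regions were named after their values had been seen.

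On each of the 19 chromosomes that are not acrocentric, the peak-free interval that spans the known hg19 centromere was taken as the centromere interval. General knowledge of the build served only to choose the interval, and its edges are the neighbouring peaks of the list. The shortest was 3.00 Mb long, and 16 of the 19 were shorter than 3.6 Mb. The 5 acrocentric chromosomes 13, 14, 15, 21 and 22 were measured from their first peak, and the others from the first base. Chromosome lengths run to the last peak and leave out the centromere interval. Other assembly gaps are unknown here and remained in the lengths. The zone next to centromeres and ends holds all peaks whose centre is within 1 Mb of an edge of a centromere interval or of an outer limit of the chromosome.

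Densities are peaks per Mb with exact Poisson 95% intervals. Ratios of densities carry exact conditional binomial intervals, and shares carry Wilson 95% intervals. All of these cover counting error only and are too narrow where peaks are grouped. Clustering was the share of peaks with another peak centre within 10 kb, set against 100 seeded random placements of the same number of peaks on each chromosome, with a two-sided permutation p whose smallest possible value is 0.0198. Bins of 1 Mb and the longest peak-free intervals were compared with 100 placements of the same kind. The best split in density along each chromosome was the one, with at least 10 Mb on each side, that most raised the Poisson likelihood, with peaks in the zones left out and the lengths of the zones kept. It was compared with the best split in each of 100 random placements, and in each of 100 sets simulated from a log-linear gradient fitted to the chromosome. Other smooth shapes were not tried. Position in the zone was compared between the 50 highest-scoring peaks and the others as an odds ratio. The zone, the top set, the splits, the bins and the peak-free intervals were chosen after the data had been seen.

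The clustering and split tests were tested on simulated data. With the real 11717 peaks placed at random, 5 of 100 runs of the clustering test gave a p under 0.05, and with 5% of the peaks moved next to another peak 20 of 20 runs did. A planted 3-fold step was found above all placements on 22 of 23 chromosomes, with a median position error of 0.361 Mb, and with no step planted 0 of 23 were called. Against the gradient, a planted 3-fold step was called on 11 of 23 chromosomes and a planted gradient on 0 of 23, so a chromosome that was not called may still hold a step. Alternatives changed the score threshold, the clustering distance, the intervals left out, the zone width and the number of top peaks. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. There is 1 peak list and no replicate of it, so each test describes this list against chance positions and carries no information on the spread between cultures.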

Results

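FOXK2 binding was profiled by ChIP-seq in untreated MCF-7 cells to find the sites and genes that this forkhead factor occupies. The MCF-7 immunoprecipitation yielded 11717 deposited peaks on the 22 autosomes, X and Y, which together covered 9.92 Mb. Peaks had a median width of 681 bp, with quartiles of 572 and 931 bp and a range from 264 to 8831 bp. The study has 1 such library, so none of the values below has a replicate check. The peak positions are those of hg19, and the genes at these positions were not analysed here.

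Most of the FOXK2 peaks had scores close to the lowest value in the list. The median score was 34.97, the upper quartile was 40.74 and the lowest was 30. A score of 50 or more was reached by 1240 peaks, which is 10.6% of the list (Wilson 95% interval 10.0 to 11.2%). A score of 100 or more was reached by 219 peaks, or 1.87% (1.64 to 2.13%), and 21 peaks exceeded 1000. Higher-scoring peaks were wider. The median width was 617 bp for the 5876 peaks that scored under 35, 1054.5 bp for the 1240 that scored 50 or more and 1253 bp for the 219 that scored 100 or more. Across peaks, which are not independent replicates, Spearman's rho between width and score was 0.36.

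**Figure D1:**
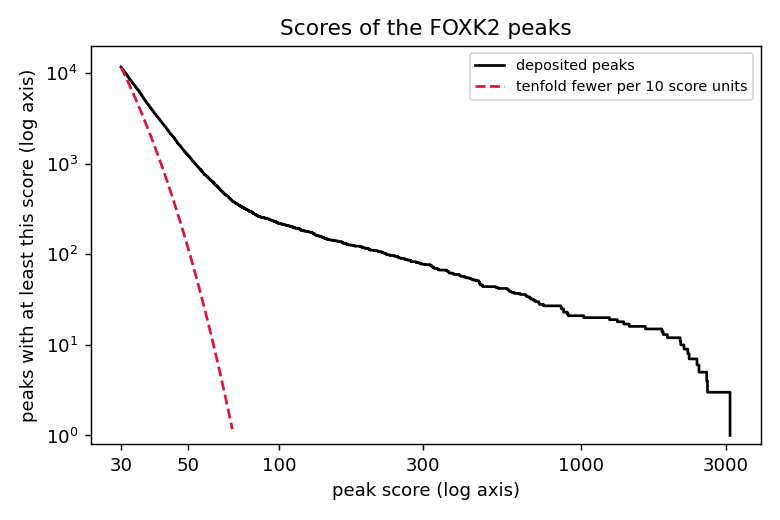
Number of FOXK2 peaks with at least a given score (solid line, both axes logarithmic), beside a line that falls to 10% per 10 score units from the same start (dashed). The list falls from 11717 peaks at a score of 30 to 1240 at 50 and 219 at 100. It lies above the dashed line at 50, and the dashed line ends before 100.

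Many of the highest scores lay beside centromeres and chromosome ends. The 3 peaks at the score of 3100 were on 6p and 9q. That on 6p, at 58775802 to 58779927, itself sets an edge of the centromere interval of chromosome 6. Those on 9q were at 66970927 to 66972794 and at 69710611 to 69711455. The next 3 were on chromosome 21 at 9826634 to 9827845 with a score of 2611, on 7q at 61967125 to 61971771 with a score of 2595, and on 10q at 42596700 to 42601464 with a score of 2447. A second peak of 9q at 67320189 to 67321337 had a score of 2410. The tip of 18p held a peak at 106524 to 111915 with a score of 2270, and 16p held one at 33962439 to 33964695 with a score of 2246. The last of the 10 highest was on 4q at 68264171 to 68266829, with a score of 2183. Of these 10 peaks, 6 lay within 1 Mb of a centromere interval or end. The other 4 were 1.28 and 3.67 Mb away on 9q, 1.32 Mb away on 16p and 15.6 Mb away on 4q.

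Of the 50 highest-scoring peaks, 28 (56.0%, Wilson 95% interval 42.3 to 68.8%) lay within 1 Mb of a centromere interval or an end, compared with 813 of the other 11667 peaks (6.97%). The odds ratio was 16.99. The width of the zone and the number of top peaks were chosen after the positions of the highest scores had been seen, so these values describe the gathering and do not test it. The zone held 9.78 peaks per Mb and the rest of the genome 3.86, a ratio of 2.53 (95% interval 2.36 to 2.72). Most edges of the zone are set by peaks of the list, which therefore lie in it by construction, so this ratio is somewhat too high. The share of peaks that scored 100 or more was 12.1% (10.1 to 14.5%) in the zone, 4.45% (2.87 to 6.85%) between 1 and 2 Mb away and 0.802% (0.628 to 1.03%) beyond 10 Mb. Outside the zone 10876 peaks remained, of which 985 scored 50 or more and 117 scored 100 or more.

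Outside the zone, the highest scores were on 9q, 16p and 4q, as above, and at single sites within chromosome arms. These further sites were chosen after their values were seen. No list of hg19 regions with known artefact signal was set against the peaks, so a high score here or above need not mark a FOXK2 site. On 1p a peak at 91852717 to 91853186 scored 2130, and on Xq a peak at 108297297 to 108298137 scored 2121. A peak on 1q at 156186183 to 156186996 scored 904. On 17q, peaks at 31149367 to 31149916 and at 41399693 to 41401226 scored 858 and 855. A further peak on 9q at 67790625 to 67792141, 1.75 Mb from the centromere interval, scored 748.7. On 14q a peak at 50052490 to 50054022 scored 726. Their widths ran from 470 bp for the site on 1p to 1534 bp for the second site on 17q.

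**Figure D2:**
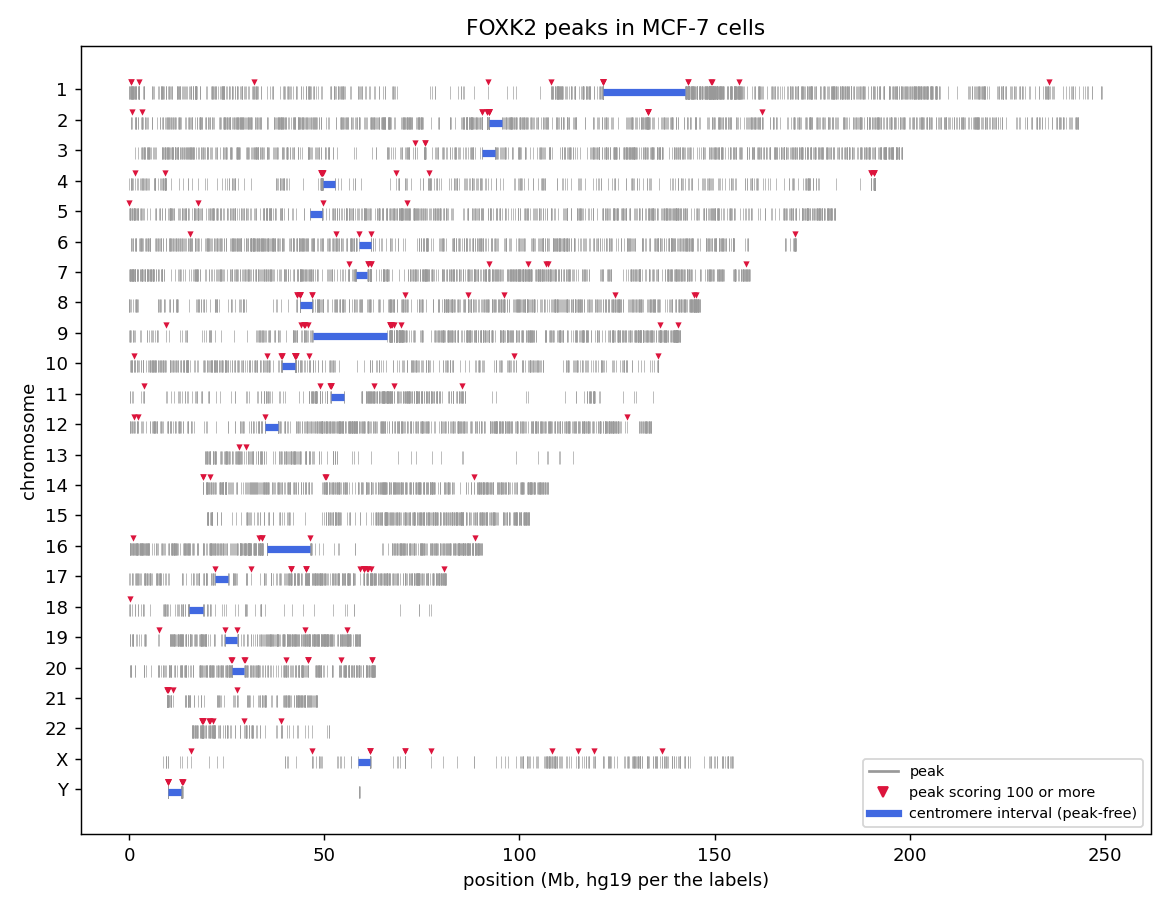
Position of every FOXK2 peak (grey ticks) along the chromosomes in Mb, with peaks scoring 100 or more as red triangles and centromere intervals as blue bars. Triangles gather at the blue bars and at some chromosome ends, and long stretches of 11q, 13q, 18q and Xp hold few ticks.

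Chromosomes differed in how densely FOXK2 peaks covered them. Over all chromosomes there were 4.03 peaks per Mb. Chromosome 19 was the densest, with 6.86 peaks per Mb (384 peaks, exact Poisson 95% interval 6.19 to 7.58), followed by chromosome 16 with 6.18 (5.64 to 6.75) and chromosome 14 with 6.004 (5.50 to 6.54). Chromosome 18 was the sparsest autosome, with 1.15 peaks per Mb (85 peaks, 0.919 to 1.42), followed by chromosome 13 with 1.85 (1.58 to 2.14) and chromosome 4 with 2.12 (1.91 to 2.34). The density of chromosome 19 was 5.96 times that of chromosome 18 (95% interval 4.70 to 7.63). With every peak-free interval of 3 Mb or more left out of the lengths this ratio was 3.79. Chromosome X held 1.57 peaks per Mb (1.38 to 1.78).

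Both arms could be compared on 18 chromosomes. The q arm was denser on 9 of them and the p arm on 5, judged by a 95% counting interval of the ratio that excludes 1, and the interval included 1 on the other 4. The widest differences in favour of the q arm were on X, with 2.18 against 0.598 peaks per Mb and a ratio of 3.65 (2.54 to 5.39), on chromosome 9, with 6.82 against 2.08 and a ratio of 3.29 (2.64 to 4.12), and on chromosome 8, with 5.24 against 1.96 and a ratio of 2.67 (2.12 to 3.40). In the other direction, 18q held 0.719 peaks per Mb and 18p 2.79, a ratio of 0.258 (0.164 to 0.403), and 10q held 2.58 against 4.98 on 10p, a ratio of 0.517 (0.426 to 0.628). Parts of 1q, 17q and 20q are known to be gained in MCF-7. The q to p ratio was 1.81 (1.59 to 2.07) on chromosome 1 and 1.62 (1.27 to 2.08) on chromosome 17, while that of chromosome 20, at 1.2 (0.957 to 1.51), did not exclude equal densities.

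**Figure D3:**
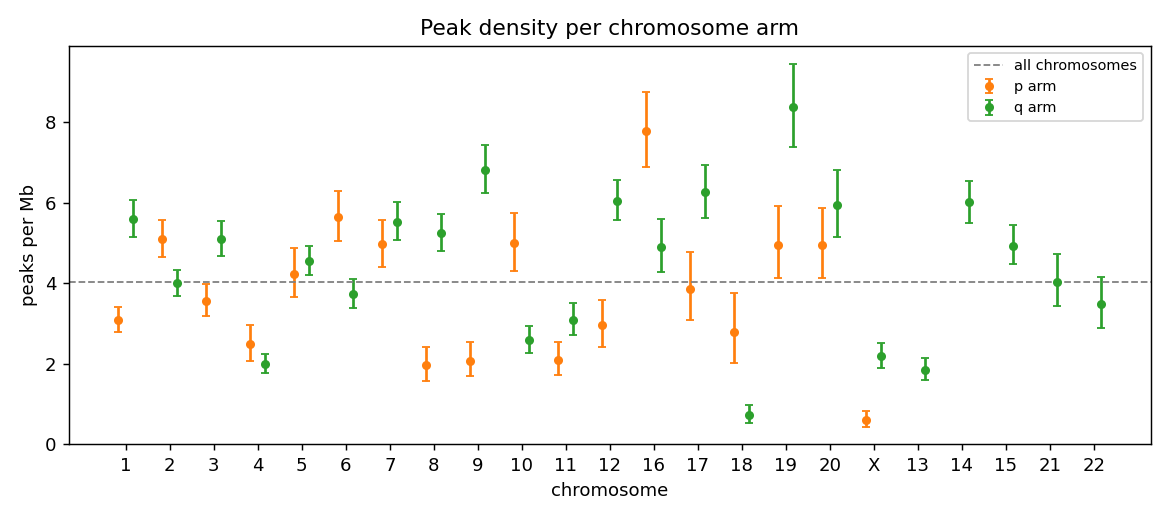
FOXK2 peaks per Mb on each p arm (orange) and q arm (green), with exact Poisson 95% intervals, and the density over all chromosomes (dashed, 4.03 peaks per Mb). The 5 acrocentric chromosomes at the right are drawn in green as a whole, measured from their first peak and not divided into arms. Among the divided chromosomes, 19q (8.36) and 16p (7.77) are the densest arms while Xp (0.598) and 18q (0.719) are the sparsest.

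Within chromosomes, peak density was uneven. On 22 of 23 chromosomes, Y not included and peaks in the zones left out, the best split into a denser and a sparser side exceeded the best split in all 100 random placements at even density, and chromosome 14 was the exception. On 12 of the 23 the split also exceeded that in all 100 sets simulated from a smooth gradient fitted to the chromosome, among them chromosomes 6, 11, 13 and X. On the other 11, among them chromosomes 9 and 22, a change at 1 position was not separated from a gradual one. Among the 12, the gradient fitted to chromosomes 4, 7, 11 and 16 was almost flat. Its gain in log likelihood over an even density was 0.315, 0.376, 0.952 and 0.00743. For these chromosomes the second comparison nearly repeats the first and does not set a step against a real gradient. Chromosome 7 passed narrowly, with a gain of 7.408 for its split against 7.377 at most in the simulated sets. The denser side held at least 3 times the density of the sparser side on 11 of the 22 chromosomes that exceeded the even placements. The densities given here divide the peaks outside the zones by the whole length on each side of the split, zones included, and are therefore somewhat too low. The random and gradient sets also covered the zones, where the list had no peaks left, which can favour a step near an end. Chromosome 4 is included in the counts of 22, 12 and 11. Its sparser side, after 176.7 Mb, held 2 peaks outside the zones. The 40 zone peaks in the bin from 190 Mb lie on that side, which is not the sparser one once they are counted. On 13q the density fell from 4.35 peaks per Mb before 53.23 Mb to 0.281 after it (147 and 17 peaks), a ratio of 15.5 (95% interval 9.34 to 27.3). On 11q it fell from 3.66 to 0.707 at 86.01 Mb (302 and 34 peaks, ratio 5.17, 3.62 to 7.61). On 6q it fell from 4.62 to 0.505 at 155.1 Mb (702 and 8 peaks, ratio 9.15, 4.62 to 21.3). On 22q it fell from 5.66 to 0.973 at 31.71 Mb (ratio 5.82, 3.52 to 10.1). In the other direction it rose at 100.1 Mb on Xq from 0.547 to 3.09 (ratio 5.66, 4.13 to 7.86) and at 41.86 Mb on 9p from 1.51 to 6.19 (ratio 4.11, 3.16 to 5.44). The intervals take the position of the split as given, which was chosen on the same peaks, and are therefore too narrow.

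Long stretches without any FOXK2 peak were also found. Leaving aside the centromere intervals, the longest peak-free interval of 23 of the 24 chromosomes was longer than in all 100 random placements, and chromosome 2 was the exception. Apart from chromosome Y, the longest were 15.9 Mb on Xp from 24073255 to 39952324, 13.6 Mb on 13q from 85439052 to 99001940, 11.7 Mb on 18q from 57581445 to 69323268, and 9.44 Mb on 11q from 102245647 to 111688563. Next came 9.43 Mb on 6q from 158648230 to 168075766 and 8.55 Mb on 1p from 68628194 to 77175503. The longest interval in the random placements was 6.13 Mb for X, 4.53 Mb for chromosome 13 and 7.81 Mb for chromosome 18. Assembly gaps other than centromeres were not removed.

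FOXK2 peaks were also more often close neighbours than randomly placed peaks. Another peak lay within 10 kb of 12.1% of the peaks, compared with a mean of 8.59% and a highest value of 9.12% in 100 placements, a ratio of 1.40 (two-sided permutation p = 0.0198, the smallest that 100 placements can give). When each peak was instead moved at random by up to 1 Mb, which keeps the regional density, the mean was 11.3%, and the ratio of 1.07 did not pass the test (two-sided permutation p = 0.099). With the zone peaks left out as well, close neighbours were rarer than after such moves, with a ratio of 0.92 (two-sided permutation p = 0.0396). Moved centres could fall closer together than the widths of the listed peaks allow, which by itself lowers these ratios. A ratio below 1 therefore does not show that peaks were spaced apart.

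The most crowded stretches lay both in the zones beside centromeres or ends and outside these zones. Of the 2391 bins of 1 Mb with a peak, 10 held more than 20 peaks, the highest number in any bin of the random placements. The bin from 190 Mb on 4q held 40 peaks, all within the zone at the end of the arm, and the bin from 49 Mb on 4p held 30, all within the zone beside the centromere. The bins from 61 Mb on 7q and from 121 Mb on 1p held 23 and 22 peaks. Of the 10 bins, 4 had no zone peak. They were on 9q from 69 Mb and on 1q from 149 Mb, with 25 peaks each, and on 16p from 30 Mb and from 33 Mb, with 21 peaks each. These 4 bins still lay within 10 Mb of a centromere interval. Its nearer edge was at 66038984 on chromosome 9, 142537007 on chromosome 1 and 35279952 on chromosome 16. They therefore do not show crowding far from centromeres.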

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

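The alternatives set beforehand for promoter shares, genes with a promoter peak, motifs (by score too) and gene lists were not run, nor were peaks per protein-coding gene, because neither sequence nor annotation of hg19 was used here. No alternative could leave out a replicate, since there is 1 library. All other alternatives were chosen after seeing the data except, for the clustering test, the peaks at or above the median score and the distance of 50 kb. The number of peaks was 1240 at a score of at least 50 and 219 at a score of at least 100. The 10 kb clustering ratio of 1.40 fell to 1.07 and lost its call when peaks were moved by up to 1 Mb, and turned to 0.92 when zone peaks were also left out. In both cases the comparison keeps regional density by construction, so the excess of neighbours in the list as a whole went largely with regional density. Moved peaks may overlap, which lowers both ratios, so the value below 1 is not read as spacing. The other clustering alternatives gave ratios from 1.24 (without zone peaks) to 2.24 (the 5867 peaks scoring at or above the median), each with a permutation p of 0.0198. The ratio of chromosome 19 to 18 moved to 3.79 with long peak-free intervals left out of the lengths, by construction, and these remained the densest and sparsest autosomes under each of the 4 alternatives. The odds ratio of the 50 highest peaks ranged from 12.51 (top 200) to 30.7 (top 20). The number of chromosomes whose best split passed fell from 22 to 12 when sets simulated from a gradient took the place of even placements. Among peaks at or above the median score, splits exceeded all placements on 20 chromosomes, all of them among the 22, and the longest peak-free interval did so on 19, of which 18 were among the 23. Depth is unknown, so how many sites lie below the score of 30 cannot be given.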

Other observations

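Peaks that scored 50 or more outside the zones beside centromeres and ends were grouped. Of the 985 stronger peaks, 6.29% had another such peak within 10 kb, compared with a mean of 0.831% in 100 random placements, a ratio of 7.58 (two-sided permutation p = 0.0198, the smallest possible). When each was moved by up to 1 Mb the mean was 1.68% and the ratio 3.76 (permutation p = 0.0198). Of the 5607 peaks under 35, 4.39% had such a neighbour, compared with 4.30% at random (permutation p = 0.871) and 5.39% after moves by up to 1 Mb, a ratio of 0.814 (permutation p = 0.0594). The difference between these classes was not itself tested. The bins of 1 Mb with the most stronger peaks outside the zones were on 16p from 33 Mb with 9, on 9q from 69 Mb with 8, and on 22q from 18 Mb and 17q from 60 Mb with 7 each, followed by 1q from 149 Mb and 5q from 140 Mb with 6 each. The highest scores in these bins ran from 66.82 on 5q to 3100 on 9q. The bins on 16p, 9q and 1q lay within 10 Mb of a centromere interval. The zones do not take in all of the excess of high scores near centromeres and ends. Between 1 and 2 Mb away 4.45% of peaks scored 100 or more, compared with 0.802% beyond 10 Mb. How much of the grouping comes from this surrounding excess was not tested.

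Chromosome Y, which MCF-7 is known to lack, held 42 peaks, all of them in the zones and 21 of them scoring 50 or more. They formed 3 groups. One of 19 peaks lay at 9924212 to 10057151, another of 19 at 13263281 to 13842889, and 4 at 58969122 to 59033304. A peak of each group sets an edge of the zones, so the place of these groups in the zones is partly by construction.

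In the weighing that follows, the tests of peak width within score strata, of peaks beyond 10 Mb and of the share of peaks that reach 40 were chosen after their results were seen; for peak width this was the ratio without strata. The first pattern is the gathering of the highest scores beside centromeres and ends. A gain of whole chromosome arms was weighed by shares pooled over all chromosomes, in which no gained arm was examined by itself. The share of peaks that scored 100 or more was 12.1% within 1 Mb, 2.56% between 1 and 5 Mb and 0.802% beyond 10 Mb. The bound set beforehand for the middle distance, a share under 0.2 of that within 1 Mb, was narrowly missed at 0.211, so that test did not decide. The share beyond 10 Mb largely restates the pattern itself and is no separate test of it. The pooled shares fell with distance, which a gain spread evenly over whole arms would not give by itself. For any particular arm a gain stays undecided. Repeated sequence that is collapsed in the reference stays open. The 42 peaks on chromosome Y, which MCF-7 is known to lack, were all in the zones, and 21 of them scored 50 or more. Their place in the zones is partly by construction, since peaks of the same groups set the edges. If the cells lacked chromosome Y, the reads under these peaks came from other sequence, but from which was not tested. They do not carry the whole pattern, since the odds ratio of the 50 highest peaks was 15.28 without chromosome Y. For the zones as a whole, collapsed repeats rest on 1 test, of peak width. Among peaks that scored under 50, those in the zones were wider than others of similar score by a ratio of 1.05 with 20 score strata (two-sided permutation p = 0.013), and by 1.04 and 1.08 with 10 and 50 strata. Without strata the ratio was 1.09, part of which goes with the higher scores in the zones. The difference is small, neighbouring peaks are not independent, and other causes could widen peaks there. No biological explanation was tested, because only 1 sample had a peak list here and neither sequence nor annotation of hg19 was used.

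The second pattern is that 89.4% of the peaks scored under 50. If the scores are 10 times the negative log10 of calibrated p-values, random background would bring 10% of the peaks to 40, and 27.2% (95% interval 26.4 to 28.0%) reached it, which argues against such background as the source of the whole list. Background that is more variable than the caller assumes stays open for the weakest peaks and is not decided by their spacing. Under 35 and outside the zones, the share with a neighbour was 1.02 times that at even density but 0.814 times that after moves by up to 1 Mb, since these peaks too follow the regional density. Real sites that are spread evenly, or neighbours joined by the caller, would look alike.

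The third pattern is the uneven density along chromosomes and between arms. That it was carried by the weakest peaks alone is argued against by a Spearman's rho of 0.721 across 41 arms between the densities of peaks under 35 and of 50 or more (permutation p = 2e-05, the smallest possible; arms are not replicates). On the 22 chromosomes whose split exceeded the even placements, with zone peaks left out, peaks of 50 or more were denser on the same side on 21. Their median ratio was 3.13, compared with 3.00 for peaks under 35. The splits and denser sides had been chosen on peaks of all scores together, so part of this agreement is built in. The median of 3.13 counts chromosome 4, which had no peak of 50 or more outside the zones on its sparser side, as the highest. That side also holds the bin from 190 Mb with 40 zone peaks, scoring up to 219.6, which were left out. A candidate explanation is DNA copy number, and the q arm was denser than the p arm on 3 of the 3 chromosomes with known q arm gains (1, 17 and 20), although the interval for chromosome 20 included 1. This is no support for that explanation, since the q arm had the higher density on 12 of all 18 chromosomes with both arms, and 27.0% of random sets of 3 of them would show the same. Copy number gains of 1q, 17q and 20q cannot be told apart from a regional difference in FOXK2 binding sites or genes, because neither read depth of the input nor gene positions were used here. For the same reason, copy number stays open for the other arms and for the sparse stretches, where it was not examined.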
